A study of Homo sapiens with 56 samples.

How the data were processed

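RNA-seq libraries of K562 cells (36) and ATAC-seq libraries of K562 clones (20) were taken as deposited. Per the submitters' processing notes, the authors used Bowtie, RSEM and DESeq2 with GRCh38 for RNA. Per the submitters' notes, the authors used Bowtie, MACS2 and DESeq2 with GRCh37 for ATAC. Versions, the annotation, the strandedness of the libraries and the strand setting of counting are not given in the sources used here. The authors deposited the RNA values as TPM per gene and library, and the file headers name them so. Each column has the same sum, values have 2 decimals, and TPM keeps no depth, so no counts, intervals or floors could be derived. The table holds 58174 genes with an Ensembl identifier and a symbol, of which 21806 are at 0 in every library.

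The ATAC file is the authors' own comparison of +/+ with -/- clones. Genotypes here follow the sample labels, since the series text places clone BH under both. Per the file headers it gives for each region the total counts, a p-value, a step-up false discovery rate and a fold change. The score of a region, its signed fold change, was deposited by the authors as a ratio of +/+ to -/-, with the inverse and a minus sign where below 1. It was converted to log2 here. The total counts deposited by the authors are a signal summed over libraries and not whole numbers. A p-value deposited by the authors for 6756 regions has no false discovery rate beside it. These had a median total of 12.7 against 98.2 in the others and were not used in tests. Which treatments and libraries entered that table is not stated. Because the file holds no values per library, the count tests planned for ATAC, the tests with clones as replicates and the hemin effect on accessibility were not run.

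RNA libraries were grouped by label into 12 groups of 3 (4 treatments by 3 sets). Genes with a mean of at least 1 TPM over the 36 libraries (14307) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend). All 12 groups shared 1 estimate of the spread, and each comparison was the mean over sets of the difference between treatments. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes. Adjusted p are Benjamini-Hochberg values with a threshold of 0.05. The comparisons were hemin minus untreated, scrambled shRNA minus hemin alone, and ARID3a shRNA minus scrambled shRNA, pooled and per set, with an F test of differences between sets. The designs, alternatives, naming rule and gene lists were fixed before the data were examined. Named genes are ARID3A, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 TPM, a symbol and the same sign in all 3 sets, and up to 4 called members of each list or, where none was called, the 2 with the highest mean TPM. Names derived from clones, such as AL355075.4, were treated as no symbol. For ATAC they are the 5 highest and 5 lowest folds and called members of the globin, heme biosynthesis, erythroid transcription factor and megakaryocyte lists. Named outside this rule, after their values were seen, were ATF4, HBQ1, HMOX1, MCM6, NPM1, RN7SK, RN7SL1, RN7SL2 and XBP1 for hemin, HBE1, HBG2, RN7SK, RN7SL1 and RN7SL2 for scrambled shRNA, HBQ1 and TAL1 for ARID3a shRNA.

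The 23 gene lists were globins, heme biosynthesis, iron uptake and storage, the heme and oxidative stress response, red cell membrane and blood group proteins, erythroid transcription factors, megakaryocyte, myeloid and lymphoid markers, mitotic cell cycle, DNA replication, ribosome biogenesis, heat shock, the ATF4 and unfolded protein response, interferon response, cholesterol synthesis, autophagy, immediate early genes, p53 targets, the ARID family, mitochondrial mRNAs, histones and housekeeping genes. They were tested with camera (correlation 0.01), camera with an estimated correlation and fry, adjusted over the 23 lists of a comparison. No camera call of any comparison held with an estimated correlation. The share of hemin genes with the opposite ARID3a shRNA sign was set against 99 permutations of labels within sets. Distances are root mean square differences of log2(TPM + 1) between a library and the mean of the other libraries of a group. They cover 10326 genes with a mean of at least 5 TPM, without mitochondrial genes and with each library's median subtracted. Libraries with a distance above 0.4 to their own group were left out in an added alternative.

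Alternatives covered the pseudocount (0.1 and 0.5), the filter (none and 5 TPM), quantile normalization, median-of-ratios scaling, only the compared groups in the fit, averages per set, a replicate block, each set and each library left out, eBayes without trend and hemin alone as the control. Added after seeing the data were TPM without mitochondrial genes, the fit without 6 libraries, array quality weights, and quantile normalization for the set differences, the lists and the opposite-sign share. Simulated changes of 0.5 and 1 log2 units were made in 100 genes each of the 14307. They were recovered in 77 and 96% of genes for hemin, 79 and 98% for scrambled shRNA, and 76 and 93% for ARID3a shRNA. In these simulations 6.49, 2.75 and 3.98% of the calls were false. Noise was drawn independently for each gene and library, so these rates do not cover variation that many genes of a library share. The share of false calls in the real data is not known from them. ATAC regions were compared between gene sections and chromosomes with Fisher's exact test (SciPy 1.17.1), and with RNA by Spearman correlation with 100000 permutations, using Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Near-identical copies (HBA1 and HBA2, HBG1 and HBG2, HSPA1A and HSPA1B, MIR3648-1 and MIR3648-2) and overlapping or antisense genes are uncertain.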

Results

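The series measured transcript levels and chromatin accessibility in K562 cells, a human leukaemia cell line that makes embryonic and fetal haemoglobin when given hemin, an iron porphyrin. ARID3a, a DNA-binding protein of the ARID family, was the target of an shRNA in the RNA experiment, and clones of the accessibility experiment carry genotype labels for it. RNA came from 36 libraries in 4 treatments: untreated cells, hemin, hemin with a scrambled shRNA and hemin with an ARID3a shRNA. Each treatment had 3 sets of 3 replicates, and the labels do not say what a set is. ATAC-seq, which reads open chromatin, came from 20 libraries of 5 clones, 2 labelled -/- and 3 labelled +/+. The design text of the series lists 1 of the clones under both genotypes, so which clones stand behind each side is uncertain. Of these only the authors' deposited table of regions compared between the genotypes was at hand. The expression values are TPM, scaled to the same sum in each library, so the sequencing depth is unknown and no counting intervals are given. Between 13087 and 14685 genes per library reached 1 TPM. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The closest pair of libraries, untreated set 3 replicates 2 and 3, differed by a root mean square of 0.348 log2 units and shared 1.32% of their values exactly.

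ARID3A (ENSG00000116017), the gene the shRNA targets, was not called by limma in any of the 3 comparisons. Its level was 49.7 ± 7.57 TPM in untreated cells, 45.8 ± 3.87 TPM with hemin, 47.6 ± 5.28 TPM with hemin and scrambled shRNA, and 43.0 ± 4.23 TPM with hemin and ARID3a shRNA (SD, n = 9 libraries each). The libraries labelled ARID3a shRNA differed from the scrambled ones by a log2 fold change of -0.14 (SE 0.06, limma adjusted p = 0.157), with 0.06, -0.31 and -0.18 in sets 1, 2 and 3. In set 2 it was at 49.4 ± 0.821 TPM with scrambled and 39.7 ± 1.73 TPM with ARID3a shRNA (n = 3 each; limma adjusted p = 0.0942). A fall of the target transcript was not detected, and these libraries are named by their label throughout. Hemin against untreated gave -0.10 (SE 0.06, limma adjusted p = 0.159), and did not pass. It passed as lower after quantile normalization (-0.29), after median-of-ratios scaling (-0.23), without mitochondrial genes (-0.24) and without untreated set 1 replicate 3 (-0.15). Scrambled shRNA against hemin alone gave 0.05 (SE 0.06, limma adjusted p = 0.676).

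**Figure D1:**
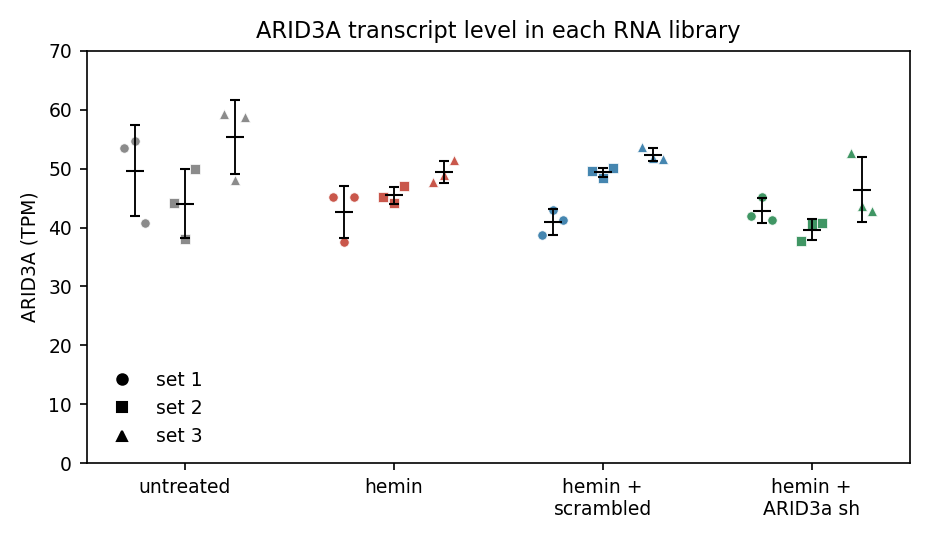
ARID3A transcript level in TPM for each of the 36 RNA libraries by treatment, with the symbol giving the set and the black bars the mean ± SD of the 3 replicates of a set. Libraries labelled ARID3a shRNA sit between 37.7 and 52.7 TPM, within the range of the libraries with scrambled shRNA except for replicate 1 of set 2. In set 2 all 3 lie below the 3 scrambled libraries of that set.

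A separate gene marked the libraries with scrambled shRNA. RPPH1 (ENSG00000277209), the RNA component of ribonuclease P, was listed at 0 in all 9 of them and between 1.07 and 82.7 TPM in the other 27 libraries. AL355075.4 (ENSG00000259001), chosen after its values were seen, was the reverse. Its values were 91.6, 127 and 83.4 TPM in the scrambled libraries of set 1, 508, 583 and 526 in set 2, and 195, 303 and 805 in set 3. They were 0 to 1.81 TPM in the other 27. Of 14307 genes tested, these 2 were the only ones whose 9 scrambled libraries lay wholly below or above the other 27. Many shRNA vectors carry the promoter of RPPH1. Whether these libraries hold vector reads, or whether both genes share reads, is not known from the sources used. The values of both genes are therefore not read as a change in the cells.

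Libraries of different treatments overlapped in their profiles. Over 10326 genes with a mean of at least 5 TPM, 12 of the 36 libraries lay nearer to another group of their set than to their own: 0 of 9 untreated, 3 of 9 hemin, 5 of 9 scrambled shRNA and 4 of 9 ARID3a shRNA. The mean of the own group rests on 2 libraries and that of another group on 3, which raises the own distance somewhat. Some margins were small, such as 0.289 against 0.285 for scrambled shRNA set 1 replicate 2. How many of the 12 rest on this was not tested. The distance to the own group was above 0.4 log2 units in 6 libraries: hemin set 2 replicate 1 (0.462), scrambled shRNA set 2 replicates 1 (0.445) and 3 (0.561), hemin set 3 replicate 2 (0.463), and ARID3a shRNA set 3 replicates 2 (0.412) and 3 (0.529). Counts without these 6 libraries, an alternative chosen after seeing the data, stand beside the results below. The 6 were picked by their distance in the same data, so leaving them out lowers the spread within groups by selection. A higher count or a kept call without them is therefore not independent support. Mitochondrial transcripts took 5.73 to 43.3% of the TPM of a library, with set medians of 22.1, 10.8 and 12.8%. Their share was 32.0% ± 10.6, 15.1% ± 4.26 and 16.1% ± 0.387 in untreated cells of sets 1 to 3 and 19.3% ± 2.33, 9.72% ± 2.11 and 12.3% ± 0.470 with hemin (SD, n = 3). The small structured RNAs RN7SK, RN7SL1 and RN7SL2 summed to 1041 ± 337 TPM in untreated cells, 3573 ± 1834 with hemin, 2178 ± 1259.5 with scrambled and 1682 ± 572 with ARID3a shRNA (SD, n = 9). With hemin limma called all 3 higher, 2.22, 1.52 and 1.61. RN7SL1 and RN7SL2 are near-identical copies whose separate levels are uncertain.

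**Figure D2:**
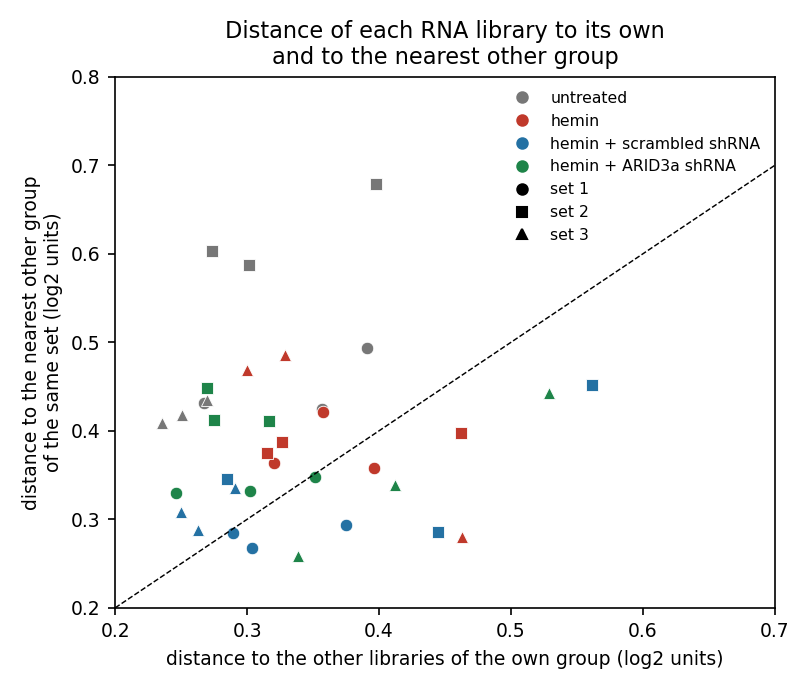
Root mean square distance in log2 units of each of the 36 RNA libraries to the other libraries of its own group (horizontal) and to the nearest other group of its set (vertical), coloured by treatment. The 12 libraries below the dashed line of equality lie nearer to another group. The mean of the own group rests on fewer libraries than that of another group, which raises the horizontal distance somewhat.

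Hemin against untreated cells asks how the cells respond to the inducer. With hemin, 7 of 8 measured globin genes rose, led by the embryonic globin HBZ (ENSG00000130656), which went from 259.5 ± 215 to 1918 ± 867 TPM (mean ± SD, n = 9; log2 fold change 3.12, SE 0.23, adjusted p = 8.53e-11 by limma). HBE1, the embryonic beta-type globin, went from 1846 ± 502 to 10506 ± 2445 TPM (2.52), HBA2 from 208 ± 114 to 1028 ± 373 TPM (2.37) and the fetal HBG2 from 3949.7 ± 1177 to 17179.8 ± 4363 TPM (2.13). HBA1 and HBA2, and HBG1 and HBG2, are near-identical copies whose separate levels are uncertain. HBQ1 gave -0.10 and did not pass the test, and it was called lower after quantile normalization. In all, limma called 8288 of 14307 genes at an adjusted p under 0.05, 5424 higher and 2864 lower, and 802 of them differed by at least 1 log2 unit (533 higher, 269 lower). Without the 6 libraries 9017 were called. The median log2 fold change over all tested genes was 0.10, against -0.01 after quantile normalization. The split became 4205 higher and 4308 lower after quantile normalization, 4305 and 4181 after median-of-ratios scaling, and 4021 and 4144 after removing mitochondrial genes. Gene lists were fixed before the data were examined, and their medians, pooled or by set, are given with that of all tested genes subtracted unless called raw. The globin median lay 1.94 above it (camera adjusted p = 1.52e-05, and adjusted p = 0.345 with an estimated correlation).

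Genes of the response to heme and oxidative stress (targets of NRF2 and BACH1) rose in 13 of 15 cases, and 1 was called lower after quantile normalization. OSGIN1 (ENSG00000140961), an oxidative stress response gene, had the highest named rise, from 13.5 ± 6.85 to 249 ± 111 TPM (log2 fold change 4.12, SE 0.26, adjusted p = 2.54e-12 by limma). NQO1 (2.56), GCLM (2.48) and TXNRD1 (1.80), enzymes of quinone reduction, glutathione synthesis and thioredoxin reduction, also rose, and the list median lay 1.14 above all genes (camera adjusted p = 2.22e-07, and adjusted p = 0.345 with an estimated correlation). The ferritin chains FTL (from 4075 ± 903 to 17810.3 ± 3744 TPM; 2.13) and FTH1 (from 5744 ± 1507 to 18665 ± 3609 TPM; 1.73) rose, while TFR2 (-0.72) and STEAP3 (-0.78) of the same list of iron genes fell. Of 12 iron genes 8 rose and 3 fell (8 and 4 adjusted over the list alone; 4 and 4 after quantile normalization), with no call for the list (camera adjusted p = 0.772). SQSTM1, an autophagy receptor, rose from 176 ± 90.0 to 1230.5 ± 423 TPM (2.96), NMRAL2P from 1.00 ± 0.441 to 14.6 ± 5.70 TPM (2.91), AKR1C1, an aldo-keto reductase, from 129 ± 34.9 to 935 ± 289 TPM (2.84), and GADD45B from 2.48 ± 1.17 to 40.1 ± 36.8 TPM (2.98). The chemokine CXCL8 rose from 1.67 ± 1.04 to 38.4 ± 11.9 TPM (3.90). MIR3648-1 and MIR3648-2, listed with identical values and so not told apart, rose by 2.89. This stands beside the higher mean sum of small structured RNAs with hemin given above, and whether it is separate was not tested. MCM5, a subunit of the replicative helicase, whose reads are not known to be its own (weighed in the closing section), rose from 70.3 ± 9.74 to 561 ± 145 TPM (log2 fold change 2.94, SE 0.18, adjusted p = 2.54e-12 by limma).

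All 11 immediate early genes rose (9 after quantile normalization), with EGR1 at 2.47, FOS at 2.18, FOSB at 2.08 and DUSP1 at 1.69 (camera adjusted p = 4.73e-04, and adjusted p = 0.674 with an estimated correlation). Of 13 heat shock genes 10 rose and 1 fell. Among them HSPH1 (1.37), BAG3 (1.33), CHORDC1 (1.25) and HSPA1A (1.25), which is nearly identical to HSPA1B, rose (camera adjusted p = 0.0228, and adjusted p = 0.753 with an estimated correlation). Of 13 measured ARID family genes 10 rose (9 higher and 2 lower after quantile normalization), among them ARID4A (0.81), ARID3B (0.78), KDM5B (0.75) and ARID4B (0.75) (camera adjusted p = 0.0228, and adjusted p = 0.753 with an estimated correlation). The medians of these 3 lists lay 1.42, 0.58 and 0.50 above that of all genes.

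Of 13 genes of the ATF4 and unfolded protein response 10 fell, with PHGDH, the first enzyme of serine synthesis, going from 154 ± 48.5 to 43.7 ± 48.1 TPM (log2 fold change -2.46, SE 0.44, adjusted p = 2.94e-05 by limma), ASNS at -1.64, TRIB3 at -1.56 and PSAT1 at -1.54. ATF4 itself (0.43) and XBP1 (0.22) rose, of which 1 did after quantile normalization. The list median lay -1.15 from that of all genes (camera adjusted p = 4.73e-04, and adjusted p = 0.345 with an estimated correlation). Other genes with the largest falls were the cytokine receptor chain IL20RB (-2.98), the urea cycle enzyme ASS1 (-2.84), AKNA (-2.80), the calcium pump ATP2A3 (-2.80), SPRR2D (-2.55), NUPR1 (-2.49), ATF5 (-2.35) and INHBE (-2.33). SNORD22 was listed at 0 in all 9 hemin libraries and above 0 in 4 of 9 untreated ones. Its call was lost without untreated replicate 2 of set 1, replicate 1 of set 2 or replicate 1 of set 3. Of 8 myeloid markers 7 fell, among them PRTN3 (-1.04), ITGAM (-0.90), CD33 (-0.89) and CSF3R (-0.89) (camera adjusted p = 0.00149, and adjusted p = 0.345 with an estimated correlation). Of 13 mitochondrial mRNAs 10 fell (9 after quantile normalization), for example MT-CO3 (-0.81) and MT-CO2 (-0.77), beside the lower mitochondrial share given above (camera adjusted p = 4.01e-04, and adjusted p = 0.674 with an estimated correlation).

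Of 16 erythroid transcription factors 7 fell and 2 rose (12 and 2 after quantile normalization), with MYB, which is high in immature cells, at -1.12, LYL1 at -0.85 and KLF1 at -0.35, while TAL1 rose by 0.46 (camera adjusted p = 0.0164, and adjusted p = 0.674 with an estimated correlation). Heme biosynthesis had 2 of 11 genes higher and 4 lower (0 and 8 after quantile normalization), with ABCB10 at -0.35 and SLC25A38 at -0.30. The rises of ALAS1 (0.39) and FECH (0.29) were lost after quantile normalization (list: camera adjusted p = 0.142). Of 24 red cell membrane and blood group genes 9 rose and 5 fell (8 and 6 after quantile normalization), with SPTA1 at 1.36, KEL at 0.89 and GYPC at -0.89 (camera adjusted p = 0.881). Of 8 megakaryocyte markers TUBB1 rose (0.65) and 3 fell (4 after quantile normalization), ITGA2B at -0.83, GP1BB at -0.69 and CD9 at -0.41 (camera adjusted p = 0.344). Of 18 DNA replication genes MCM5, uncertain as above, and MCM6 (0.25) rose and 5 fell (1 and 10 after quantile normalization), with CDT1 at -0.88, TYMS at -0.31 and GINS2 at -0.31. The list's median lay -0.17 from that of all genes, its raw mean was 0.08 and its test pointed down (camera adjusted p = 0.344). Of 18 mitotic genes 7 rose and 2 fell (4 and 6 after quantile normalization), CDC20 at 0.53 and AURKB at -0.45 (camera adjusted p = 0.831). Of 18 ribosome biogenesis genes 8 rose and 3 fell (6 and 5), PES1 at 0.69 and NPM1 at -0.43 (camera adjusted p = 0.553).

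**Figure D3:**
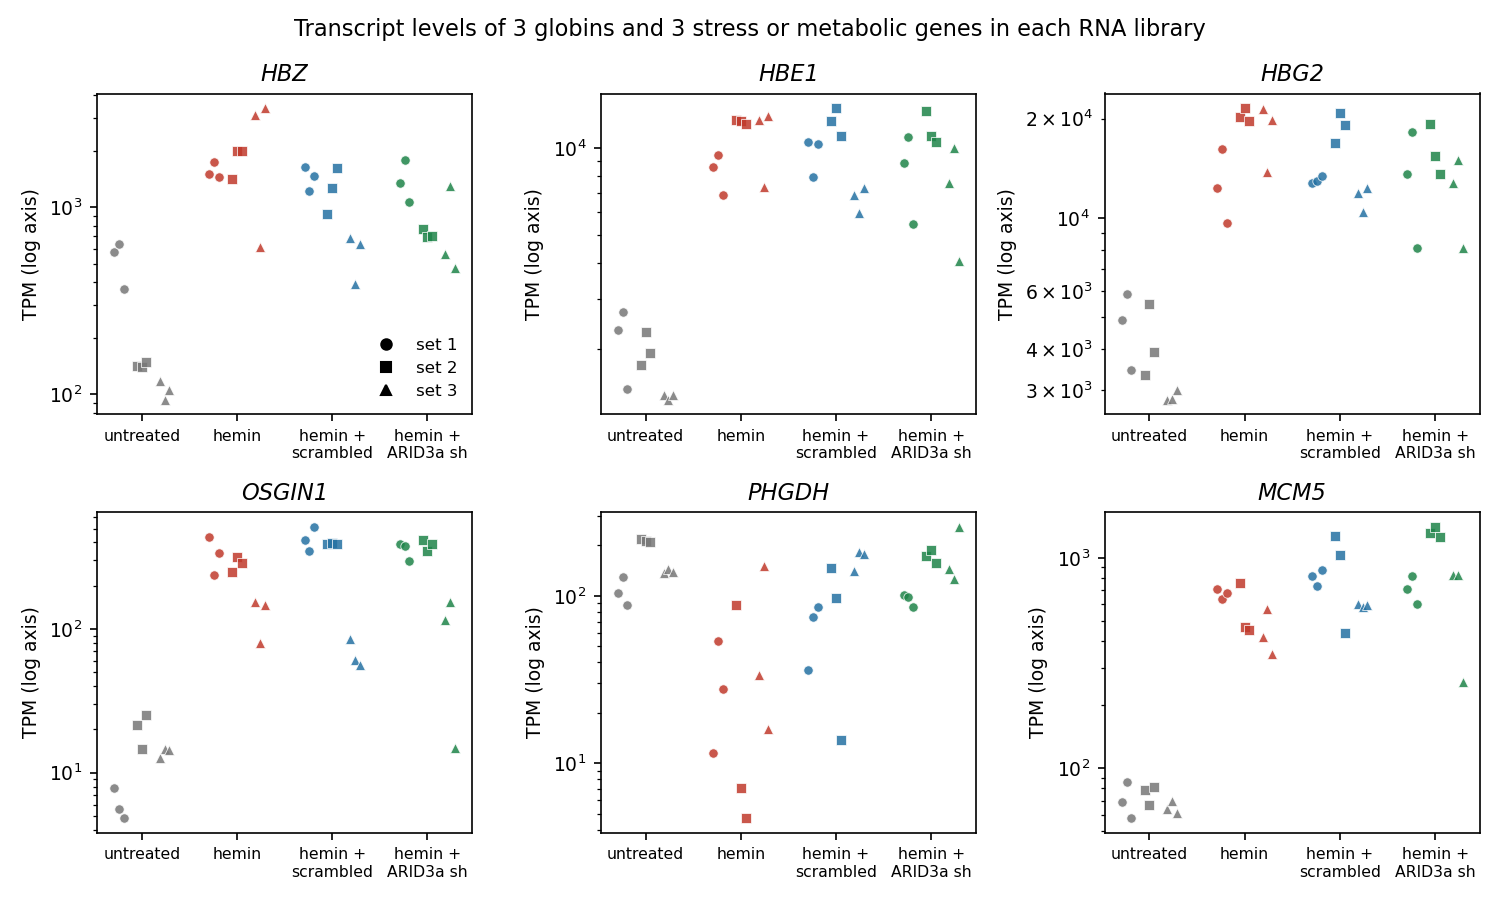
TPM on a log axis of HBZ, HBE1, HBG2, OSGIN1, PHGDH and MCM5 (its level uncertain, as in the text) in each of the 36 RNA libraries by treatment, with the symbol giving the set. HBE1, HBG2 and MCM5 lie higher in each of the 27 libraries with hemin than in the 9 untreated ones, while HBZ, OSGIN1 and PHGDH overlap.

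The hemin effect was called for 3871, 6734 and 4349 genes in sets 1, 2 and 3, and 1281 genes were higher and 308 lower in all 3. Log2 fold changes correlated across genes, which are not independent replicates, at a Pearson r of 0.619 between sets 1 and 2, 0.534 between 1 and 3 and 0.758 between 2 and 3. The effect differed between sets for 789 genes in limma's F test. Without 1 library the counts per set moved by over 1.5 times in set 1 without hemin replicate 1 (2286) and in set 3 without hemin replicates 1 (2521) and 3 (2464). With replicates averaged per set, 5401 genes were called.

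Scrambled shRNA with hemin against hemin alone is by design the control for shRNA delivery. The ARID3a shRNA libraries did not share the values that marked the scrambled ones, with AL355075.4 at 0 to 1.81 TPM and RPPH1 at 3.76 to 36.4 TPM. Nothing at hand shows delivery of the ARID3a shRNA, so whether both shRNA arms match in this is not known. Both the scrambled comparison and that of hemin with untreated cells use the same 9 hemin libraries. Opposite signs of a gene in both are therefore not independent. NUPR1 went from 8.86 ± 13.3 to 38.5 ± 34.5 TPM (mean ± SD, n = 9; log2 fold change 2.05, SE 0.40, adjusted p = 0.00599 by limma), and PHGDH (1.67), ASS1 (1.65), INHBE (1.61), IL20RB (1.51), AKNA (1.31) and ATF5 (1.18) were called higher. S100P (2.02), the folate enzyme ALDH1L2 (1.21) and ACP5 (1.11) also rose. RPPH1, at 0 in these libraries, was called lower. The small nucleolar RNA SNORA73A (-2.02), RMRP, the RNA of ribonuclease MRP (-1.16), and the arrestin genes TXNIP (log2 fold change -1.58, SE 0.29, adjusted p = 0.00454 by limma) and ARRDC4 (-1.42) fell. Of the small structured RNAs above, RN7SL2 was also called lower (-0.70), while RN7SL1 (-0.62) and RN7SK (-0.80) did not pass the test. The falls of SNORA73A and RMRP thus stand beside a lower mean sum of other small RNAs, and whether they are separate from it was not tested. SERTAD1 (-1.05), HYPK (-1.04), KLF10 (-0.95) and EGR1 (-1.50) fell. Of 14307 genes 769 were called, 450 higher and 319 lower (639 and 750 after quantile normalization, 552 and 645 after median-of-ratios scaling), and 30 by at least 1 log2 unit (18 higher, 12 lower). Without the 6 libraries far from their group 3072 genes were called, and all 42 named genes kept their call. As said above, this is not independent support. All 42 also stayed called after quantile normalization and after median-of-ratios scaling. Other settings ended many of these calls: 29 with only the compared groups in the fit, 16 with no filter on low values and 41 with averages per set. Leaving out sets 1, 2 and 3 ended 27, 14 and 35. In all 3 sets only RPPH1 and AL355075.4 were called.

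Among the lists, 3 of 8 globins fell with the scrambled shRNA: HBA2 from 1028 ± 373 to 576 ± 261 TPM (-0.91), HBZ (-0.80) and HBA1 (-0.71) (camera adjusted p = 0.00172, and adjusted p = 0.623 with an estimated correlation). By set, HBA2 gave -0.28, -0.50 and -1.94, and the list median was 0.03, -0.12 and -0.77 in sets 1, 2 and 3. HBE1 (-0.15) and HBG2 (-0.23) did not pass the test. Of 18 ribosome biogenesis genes 7 fell, 11 adjusted over the list alone, among them ODC1, of polyamine synthesis (-0.66), RRP9 (-0.44), NOP16 (-0.43) and RRS1 (-0.32) (camera adjusted p = 4.39e-08, and adjusted p = 0.287 with an estimated correlation). Of 13 ATF4 and unfolded protein response genes 4 rose, 9 adjusted over the list alone, with PHGDH, HERPUD1 (0.85), TRIB3 (0.82) and HSPA5 (0.76) (camera adjusted p = 3.37e-05, and adjusted p = 0.287 with an estimated correlation). Of 11 immediate early genes EGR1 and JUNB (-0.83) fell, 6 adjusted over the list alone (camera adjusted p = 3.37e-05, and adjusted p = 0.630 with an estimated correlation). Of 15 heme and oxidative stress genes SLC7A11 (0.59), SLC48A1 (0.46) and PIR (0.43) rose (camera adjusted p = 0.0116, and adjusted p = 0.630 with an estimated correlation). The medians of this list were 0.38, 0.47 and -0.21 in sets 1, 2 and 3. Calls as lower were made for the mitotic list, of whose 18 genes CDC20 fell (-0.26; camera adjusted p = 0.0439, and adjusted p = 0.630 with an estimated correlation), and the cholesterol list, of whose 12 genes HMGCS1 fell (-0.52; camera adjusted p = 0.0409, and adjusted p = 0.630 with an estimated correlation). Among lists without a call the haemoglobin chaperone AHSP (-0.83), HEMGN (-0.56), SPTB (-0.34) and the erythroid cofactor LMO2 (-0.33) fell. GADD45A (-0.25) fell, and TP53INP1 (0.61) and CALCOCO2 (0.43) rose. The other 16 lists had camera adjusted p of at least 0.103, and raw median, raw mean or test differed in sign for the DNA replication, lymphoid, heat shock, interferon and p53 lists.

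The scrambled shRNA effect was called for 26, 11 and 295 genes in sets 1, 2 and 3, and RPPH1 and AL355075.4 were the only genes called in all 3 sets and with replicates averaged per set. Of the 42 named genes 18 kept their call in every fit that left out 1 library, NUPR1, S100P, INHBE, IL20RB, RPPH1, TXNIP, ARRDC4, KLF10, HBA2, HBA1, AHSP, LMO2, ODC1, NOP16, RRS1, HERPUD1, HSPA5 and TP53INP1. Fold changes correlated across genes at a Pearson r of 0.268, 0.249 and 0.250 between pairs of sets. No gene differed between sets in limma's F test, and 1354 did at an unadjusted p under 0.05. Leaving out 1 library gave 251 to 1988 genes, and moves of over 1.5 times came in set 1 without hemin set 1 replicate 1 (356), scrambled shRNA set 1 replicates 1 (1605), 2 (418) and 3 (253). In set 2 they came without hemin set 2 replicates 1 (1632), 2 (345) and 3 (343), scrambled shRNA set 2 replicates 1 (256), 2 (493) and 3 (1988). In set 3 they came without hemin set 3 replicates 1 (304), 2 (1556) and 3 (251) and scrambled shRNA set 3 replicates 2 (394) and 3 (345). In the fit for set 1 they came without hemin replicates 1 (2), 2 (105) and 3 (2) and scrambled shRNA replicates 1 (605), 2 (3) and 3 (2). In the fit for set 2 they came without hemin replicates 2 (2) and 3 (2) and scrambled shRNA replicates 1 (3) and 3 (105). In the fit for set 3 they came without hemin replicates 1 (10), 2 (1465) and 3 (6) and scrambled shRNA replicates 1 (124), 2 (25) and 3 (38).

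The libraries labelled ARID3a shRNA against scrambled shRNA address what the ARID3a shRNA does in hemin-treated cells. This holds only as far as both shRNA arms match in delivery, which is not known. Globin levels did not differ detectably: HBG2 was at 14514 ± 3562 TPM with scrambled and 13776 ± 3858 TPM with ARID3a shRNA (mean ± SD, n = 9; log2 fold change -0.10, SE 0.15, adjusted p = 0.724 by limma), and HBE1 gave -0.10. Of 8 globins 0 were called by limma, and 1 had an unadjusted p under 0.05, HBQ1 (0.33; adjusted p = 0.0658), which was called higher after quantile normalization. Of 16 erythroid transcription factors 5 fell, 7 adjusted over the list alone (3 after quantile normalization and 2 after median-of-ratios scaling). They were GATA2 from 88.6 ± 31.1 to 65.7 ± 27.7 TPM (log2 fold change -0.45, SE 0.07, adjusted p = 0.00295 by limma), LDB1 (-0.42), KLF1 (-0.40), NFE2 (-0.39) and TAL1 (-0.31). The list was called lower (camera adjusted p = 0.0228, and adjusted p = 0.644 with an estimated correlation), with medians of -0.01, -0.22 and -0.10 in sets 1, 2 and 3. Of its genes LDB1 alone kept its call without the 6 libraries far from their group. The transferrin receptor TFRC fell from 233 ± 55.5 to 178 ± 57.3 TPM (log2 fold change -0.41, SE 0.07, adjusted p = 0.00726 by limma), and SLC4A1, the red cell anion exchanger (-0.64), HEMGN (-0.59), KEL (-0.43) and ANK1 (-0.30) fell. Of these 4 red cell genes, SLC4A1 and HEMGN stayed called after quantile normalization and 0 after median-of-ratios scaling. The heme synthesis enzymes ALAS1 (-0.47) and HMBS (-0.33) fell, ALAS1 alone after quantile normalization and 0 after median-of-ratios scaling.

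In this comparison limma called 1020 of 14307 genes, 32 higher and 988 lower. This split depended on scaling: it was 145 and 195 after quantile normalization, 59 and 106 after median-of-ratios scaling, and 45 and 325 after removing mitochondrial genes. Only 6 genes differed by at least 1 log2 unit: RPPH1, uncertain as above, was higher, and AL355075.4, SNRPGP9, LSMEM1 (-1.21), the differentiation inhibitor ID2 (-1.09) and RN7SL417P were lower (SNRPGP9, RN7SL417P and AL355075.4 chosen after their values were seen). Other falls among the largest were DUSP8 (-0.96), the RNA host gene SNHG12 (-0.93), the enolase ENO3 (-0.84), MUC1, from 19.9 ± 9.47 to 11.6 ± 6.41 TPM (-0.81), NPPA-AS1 (-0.80), PPP1R10 (-0.77), ZGLP1 (-0.76) and POLR2A, the large subunit of RNA polymerase II (-0.75). Strand use in counting is not stated, so the level of NPPA-AS1, an antisense gene, is uncertain. Besides RPPH1 the largest rises were MCRIP1 (0.61), BEX2 (0.55), VCX (0.50), the cold-inducible RBM3 (0.49), LINC01666 (0.48), GOLGA2P10 (0.46), C9orf16 (0.40), HMGN2 (0.39) and SUPT3H (0.39).

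Without the 6 libraries far from their group 33 genes were called, and 11 of the 45 named genes kept their call: RPPH1, MCRIP1, MUC1, HMBS, TFRC, SLC4A1, HEMGN, LDB1, TUBB1, PCSK9 and INSIG1. Quantile normalization ended 21 and median-of-ratios scaling 28 of the 45 calls, with no change of sign. Only the compared groups in the fit ended 39 and no filter on low values 30, while leaving out sets 1, 2 and 3 ended 36, 44 and 18. Of the 10 largest named falls ENO3, MUC1 and SNHG12 stayed called after quantile normalization, and ENO3 and MUC1 after median-of-ratios scaling. Calls for RPPH1, RBM3, ENO3, MUC1, TFRC, GATA2, LDB1 and NFE2 stood in every fit that left out 1 library. By set the comparison called 3 genes in set 1 (RPPH1, AL355075.4 and TSEN54, the last chosen after its values were seen), 386 in set 2 (86 higher, 300 lower) and 2 in set 3 (RPPH1 and AL355075.4). These 2 were also the only genes called without set 2 and with replicates averaged per set. Fold changes correlated across genes at a Pearson r of 0.329 between sets 1 and 2, 0.0887 between 1 and 3 and 0.117 between 2 and 3. In limma's F test 0 genes differed between sets, and 1218 did at an unadjusted p under 0.05. Leaving out 1 library gave 114 to 1824 genes, and moves of over 1.5 times came in set 1 without scrambled shRNA set 1 replicate 1 (158), ARID3a shRNA set 1 replicates 1 (463) and 3 (418). In set 2 they came without scrambled shRNA set 2 replicates 1 (1824), 2 (506) and 3 (361), ARID3a shRNA set 2 replicates 1 (568), 2 (431) and 3 (577). In set 3 they came without scrambled shRNA set 3 replicates 1 (114) and 2 (503) and ARID3a shRNA set 3 replicates 1 (1635) and 3 (226). In the fit for set 1 they came without scrambled shRNA replicates 1 (1) and 3 (10) and ARID3a shRNA replicate 2 (1). In the fit for set 2 they came without scrambled shRNA replicates 1 (2098), 2 (56) and 3 (18) and ARID3a shRNA replicates 1 (90), 2 (14) and 3 (15). In the fit for set 3 they came without ARID3a shRNA replicate 3 (5).

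The ARID family list was called lower (camera adjusted p = 0.00795, and adjusted p = 0.644 with an estimated correlation), and 4 of its 13 genes fell, 5 adjusted over the list alone and 1 after quantile normalization. These were KDM5B (-0.48), ARID4B (-0.46), ARID4A (-0.46) and KDM5A (-0.45). Of 12 cholesterol synthesis genes 3 fell, 9 adjusted over the list alone and 0 after quantile normalization, PCSK9 (-0.37), INSIG1 (-0.31) and DHCR7 (-0.23) (camera adjusted p = 0.0226, and adjusted p = 0.644 with an estimated correlation). The immediate early list was called lower with 0 of 11 genes called by limma, 3 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.0235, and adjusted p = 0.725 with an estimated correlation). Its medians were -0.48, -0.71 and 0.16 in sets 1, 2 and 3. Lists called higher with 0 genes called by limma were 3. The heme and oxidative stress genes had 0 of 15 at an unadjusted p under 0.05 and medians of 0.01, 0.30 and 0.13 in sets 1, 2 and 3 (camera adjusted p = 0.00795, and adjusted p = 0.644 with an estimated correlation). The ATF4 and unfolded protein response had 0 of 13, with HSPA5 at 0.23 and medians of 0.26, 0.68 and 0.15 (camera adjusted p = 0.00600, and adjusted p = 0.644 with an estimated correlation). The mitochondrial mRNAs had 2 of 13, with MT-CO2 at 0.24 and medians of 0.23, 0.49 and 0.03 (camera adjusted p = 3.19e-04, and adjusted p = 0.644 with an estimated correlation). The mitotic list was called higher although its only called gene, the ubiquitin-conjugating enzyme UBE2C, fell (-0.79), and its medians were 0.15, 0.04 and 0.08 (camera adjusted p = 0.0228, and adjusted p = 0.644 with an estimated correlation). Among the 15 lists with no call, TFRC, TFR2 (-0.26) and NCOA4 (-0.21) of 12 iron genes fell (5 adjusted over the list alone, and TFRC alone after quantile normalization), as did 4 of 24 red cell genes (8 alone) and 2 of 11 heme biosynthesis genes (2 alone). Also lower were TUBB1 of 8 megakaryocyte markers (-0.48), NOP56 of 18 ribosome biogenesis genes (-0.50) and CHORDC1 of 13 heat shock genes (-0.58). GDF15, of the p53 list, rose (0.30). Raw median, raw mean or test differed in sign for the globin, DNA replication, myeloid, interferon, autophagy, p53, histone and housekeeping lists.

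**Figure D4:**
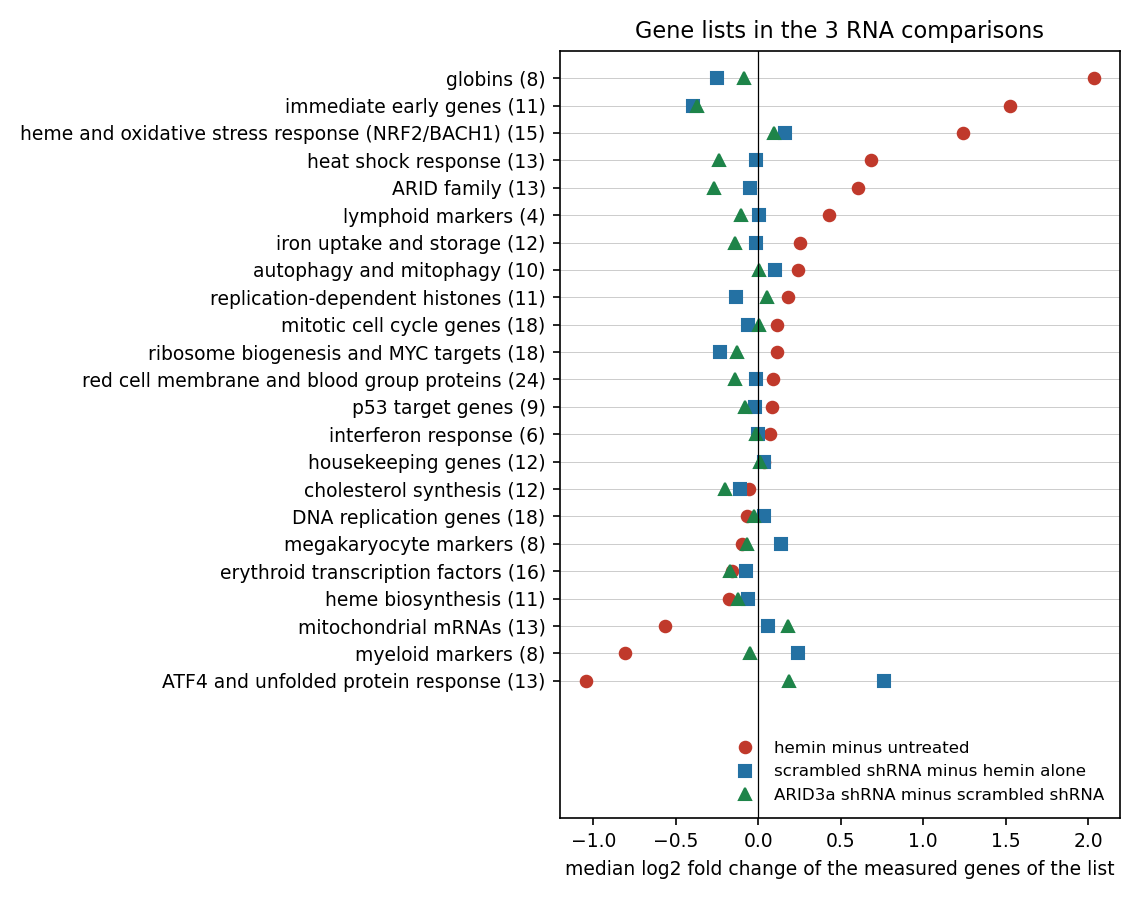
Raw median log2 fold change of the measured genes of each of the 23 gene lists (number of measured genes in brackets) for hemin minus untreated, scrambled shRNA minus hemin alone and ARID3a shRNA minus scrambled shRNA. With hemin the raw globin median is 2.04 and that of the ATF4 and unfolded protein response -1.05; in the ARID3a shRNA comparison every raw median lies between -0.37 and 0.19.

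Whether the ARID3a shRNA effect ran against the hemin effect was tested over the 8288 genes called for hemin, using effects that share no libraries. Of these genes 77.6% had the opposite sign in the ARID3a shRNA comparison. In 99 permutations of the ARID3a and scrambled labels within sets the share had a median of 51.9% and ranged from 14.7 to 88.2%, and 16 of 100 values, the real one included, were as large. The share was thus within what exchanged labels gave. It was 87.0% for genes higher and 59.5% for genes lower with hemin, against 75.5 and 74.9% after quantile normalization.

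Accessibility in clones labelled +/+ against -/- is described from the authors' deposited table alone, in GRCh37 positions, where a positive fold means higher in +/+. The authors' deposited table lists 34845 regions, of which 699 have a false discovery rate below 0.05, 231 positive and 468 negative. The highest positive folds in the authors' deposited table were 13.5 at 8:33872440-33872991, 13.1 at 13:82849663-82850771, 6.60 at X:4723446-4724113, 6.60 at 2:197078037-197078757 in intron 28 of the ubiquitin ligase gene HECW2, and 5.94 at 6:67658562-67659508, the others being intergenic. The lowest folds in the authors' deposited table were -31.8 at 4:187565257-187566304 in intron 3 of the cadherin gene FAT1, -21.7 at 4:154000848-154001603, -13.0 at 2:12394655-12395504 in a 5' UTR exon of MIR3681HG, -10.7 at 1:159923649-159924447 at the start site of SLAMF9, and -10.4 at 12:76345698-76346383. All these highest and lowest folds rest on low signal. Their total counts in the authors' deposited table were 27.5 to 72.1, against a median of 98.2 over regions with a false discovery rate. Whether a fold rests on 1 clone cannot be seen without values per library. No region of a globin or erythroid transcription factor gene is below 0.05 in the authors' deposited table, which holds 0 regions of ARID3A itself. Of the other lists, the authors' deposited table calls the start site of SLC25A38, of heme synthesis (fold 1.48, 3:39424390-39426331), and that of PHGDH (2.35, 1:120254506-120256468) as positive. Negative in the authors' deposited table were intron 1 of the platelet tubulin gene TUBB1 (-2.57, 20:57595945-57597287), coding exon 3 of the heat shock gene DNAJB1 (-8.63, 19:14626730-14627944), the end of INSIG1 (-2.16, 7:155101993-155103627) and the start site of ARID1A (-2.40, 1:27020628-27022620). Total counts in the authors' deposited table were 597 for SLC25A38, 254 for PHGDH, 81.1 for TUBB1, 39.2 for DNAJB1, 128 for INSIG1 and 137 for ARID1A. Of these, PHGDH, DNAJB1, INSIG1 and ARID1A were chosen after their values were seen.

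Called regions were unevenly spread over gene parts and chromosomes in the authors' deposited table. Start sites held fewer negative calls than other sections in the authors' deposited table, 53 of 9554 or 0.555% against 2.24% (Fisher's exact test, two-sided, adjusted p = 1.00e-28 over 14 tests), and intergenic regions more, 230 of 8756 or 2.63% against 1.23% (adjusted p = 2.47e-15). Introns held fewer positive calls in the authors' deposited table, 16 of 4129 or 0.388% against 0.897% (Fisher's exact test, adjusted p = 0.00169). On chromosome 22 the authors' deposited table calls 32 of 670 regions, all negative, or 4.78% against 2.43% elsewhere (Fisher's exact test, adjusted p = 0.0131 over 23 chromosomes), and the median log2 fold of its 670 regions was -0.45. Most of these lie in 1 stretch: 508 regions of the authors' deposited table fall in 22:20000001-25000000, with 27 called and a median of -0.48. This median is not the lowest: 8 bins of 5 Mb on other chromosomes, with at least 20 regions each in the authors' deposited table, had lower ones, down to -0.56 with 0 to 3 calls. Medians in the authors' deposited table were -0.36 on chromosome 17, -0.29 on 19, -0.19 on 16, 0.14 on 5 and 0.13 on X. Regions are not independent replicates, so these tests describe the table and not the spread between clones.

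**Figure D5:**
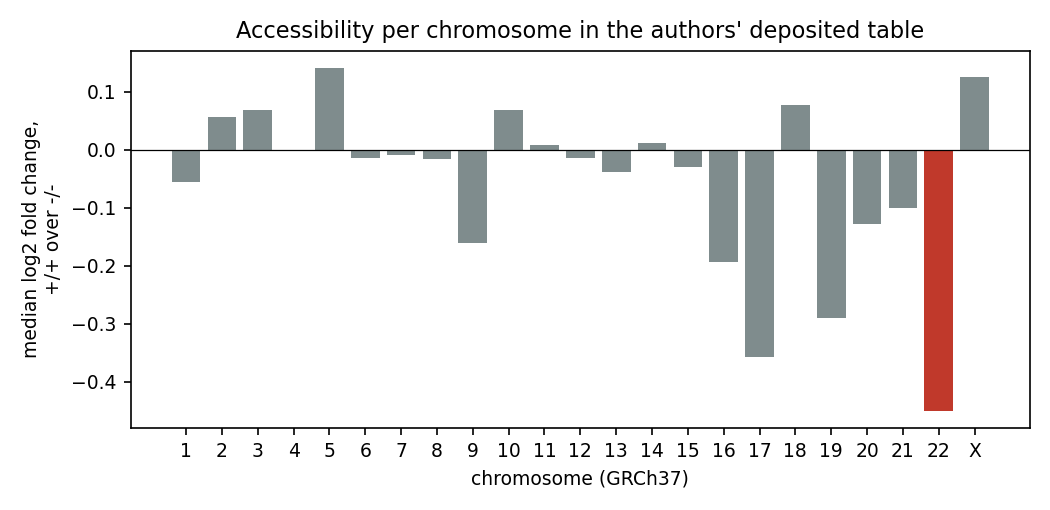
Median log2 fold of all regions with a false discovery rate per chromosome (GRCh37) in the authors' deposited table, +/+ over -/-. Chromosome 22, in red, has the lowest median at -0.45.

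Accessibility and expression were set against each other in 7878 genes with a value in both, to ask whether genes less open in -/- clones were lower in libraries labelled ARID3a shRNA. Since the fold of the authors' deposited table is +/+ over -/-, a shared direction would give a negative correlation. The Spearman correlation across genes, which are not independent replicates, was 0.1004 with the region of smallest p per gene in the authors' deposited table (permutation p = 1e-05, the smallest 100000 permutations can give; adjusted p = 1.33e-05 over 4 relations). This correlation was weak and opposite to a shared direction. Genes more open in -/- clones tended slightly to be lower in libraries labelled ARID3a shRNA. With the hemin effect in place of the ARID3a shRNA effect it was -0.036 (permutation p = 0.00134, adjusted p = 0.00134). Of 650 genes lower and 128 with a negative region in the authors' deposited table, 14 were shared, against 10.6 for independent lists (Fisher's exact test, two-sided, p = 0.256, adjusted p = 0.342). Of 650 genes lower and 79 with a positive region in the authors' deposited table, 3 were shared, against 6.52 (Fisher's exact test, p = 0.213, adjusted p = 0.342).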

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

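The F test of differences between sets was planned, while the counts of other splits of the libraries were chosen after the results were seen. Hemin changed 789 genes by amounts that differed between sets (limma F test, 14307 genes, adjusted p under 0.05), and 13 named genes are among them. HBZ rose by 1.60, 3.63 and 4.13 log2 units in sets 1, 2 and 3 (adjusted p = 0.0157 for the difference by limma), and HBA2 by 1.37, 2.64 and 3.11 (adjusted p = 0.0346). The oxidative stress gene OSGIN1 rose by 5.56, 3.76 and 3.04 (adjusted p = 0.0349) and SQSTM1 by 3.93, 3.10 and 1.85 (adjusted p = 0.0150), both the reverse order of sets to the globins. MIR3648-1 and MIR3648-2, not tested apart from the rise of the small structured RNAs, gave 0.33, 4.82 and 3.52 (adjusted p = 0.0433 by limma for each). SPRR2D changed by -1.15, -3.58 and -2.93 (adjusted p = 0.0443) and the iron reductase STEAP3 by -0.10, -1.15 and -1.08 (adjusted p = 0.0108 by limma). CA1, a red cell carbonic anhydrase, gave -0.13, 0.40 and 1.62 (adjusted p = 0.0252), KLF1 0.16, -0.81 and -0.40 (adjusted p = 0.0480) and CD9 0.24, -0.60 and -0.86 (adjusted p = 0.0328 by limma). RRP9 gave 1.06, 0.12 and 0.23 (adjusted p = 0.0469) and the histone gene HIST1H3B -0.20, 1.99 and 1.28 (adjusted p = 0.00208 by limma). The labels do not say how the sets differ, so no biological explanation was tested. For the differences between sets, 10 of 100 splits of the libraries, the real one included, gave as many genes as 789. The highest other gave 4321. Labels were exchanged within each set, so a split that mixes the sets unequally turns the hemin effect itself into a difference between sets. These splits are thus no measure of chance for this count, and whether chance gave it stays undecided.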

How the results depend on the processing

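Removal of mitochondrial genes, the fit without 6 libraries, array quality weights, and quantile normalization for set differences, lists and the opposite-sign share, and permuted replicate numbers, were chosen after seeing the data. The hemin count of 8288 stayed within 1.5 times under each alternative listed in the processing summary except averages per set (5401). Leaving out 1 library gave 7779 to 8475. The causes of the moves below were not tested, except that fewer libraries or genes enter where sets, libraries or groups are left out.

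The scrambled shRNA count of 769 became 402 with no filter on low values, 1389 after quantile normalization, 1197 after median-of-ratios scaling, 268 with only the compared groups in the fit, 2 with averages per set, 278, 484 and 84 without sets 1, 2 and 3, and 3072 without the 6 libraries. Leaving out 1 library gave 251 to 1988, as named in the report. The ARID3a shRNA count of 1020 became 339 with no filter, 340 after quantile normalization, 165 after median-of-ratios scaling, 28 with only the compared groups, 2 with averages per set, 119, 2 and 465 without sets 1, 2 and 3, 5248 against hemin alone, 370 after removing mitochondrial genes, and 33 without the 6 libraries. Leaving out 1 library gave 114 to 1824. Array quality weights gave 7368 and 4541 genes; their estimation did not converge (1 library had a weight of 233), so these counts are not to be relied on. Against hemin alone RPPH1 turned to -0.95, because the scrambled libraries, at 0, were no longer the control.

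Per set, leaving out 1 library gave 2286 to 4072, 5223 to 7096 and 2464 to 5035 genes for hemin in sets 1, 2 and 3, 2 to 605, 2 to 105 and 6 to 1465 for scrambled shRNA, and 1 to 10, 14 to 2098 and 2 to 5 for ARID3a shRNA. A pseudocount of 0.1 gave 9 and 179 genes for scrambled shRNA in sets 1 and 3. With only the samples of that set in the fit, scrambled shRNA gave 2, 6 and 28 genes and ARID3a shRNA 1 and 4 in sets 1 and 2. Without the 6 libraries the scrambled counts were 271, 193 and 2768 in sets 1, 2 and 3, and the ARID3a counts 93 and 4 in sets 2 and 3; fits that leave an arm with 1 library assume that it varies like the others. Set differences became 1414 for hemin and 2 for ARID3a shRNA (HK2 and NET1, chosen after their values were seen) after quantile normalization.

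The count of lists called was 9, 7 and 8 with camera in the 3 comparisons, 0 in each with an estimated correlation, 15, 2 and 2 with fry, which asks whether a list moves on balance, and 5 for ARID3a shRNA after quantile normalization. The ATAC count of 699 in the authors' deposited table became 227 below 0.01. The opposite-sign share of 77.6% was 80.03% at an adjusted p under 0.01, 75.2% after quantile normalization and 69.1% without the 6 libraries. The correlation of 0.1004 kept its sign in its alternatives (0.1097 with the mean over regions and 0.0795 with hemin alone as the control). Over the named genes, fits leaving out 1 library ended 5 calls and left 1867 for hemin, 193 and 563 for scrambled shRNA, and 282 and 528 for ARID3a shRNA. The other alternatives ended 54 and left 1601, 167 and 504, and 318 and 445. The replicate block gave 8408, 1053 and 1344 genes. Replicate numbers were not taken to pair the samples, since correlations of same-numbered libraries ranged from -0.374 to 0.488 (mean 0.033, 54 pairs). As a hint from the data, 19 of 36 libraries correlated best with their own number, against a median of 12 with permuted numbers (permutation p = 0.0548), so pairing is not excluded. Planned ATAC count, clone and hemin tests were not run, since the file holds no values per library. TPM hides depth, so low genes are limited to an unknown degree.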

Other observations

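The counts of other splits of the libraries and the tests of the RPPH1 labels, of GC content on its own and of copy number as a sole cause were chosen only after the result was seen. Lists in the hemin comparison not described above had no camera call, though single members changed. Of 9 p53 target genes 3 rose and 2 fell (2 and 2 after quantile normalization). CDKN1A (0.73) and MDM2 (0.52) rose, and the apoptosis gene BBC3 (-0.85) and TP53INP1 (-0.42) fell (camera adjusted p = 0.955). Of 10 autophagy genes 5 rose and 2 fell (4 and 4 after quantile normalization), with GABARAPL1 at 1.38, ATG14 at 0.97 and WIPI1 at -1.05 (camera adjusted p = 0.542). IRF7 (0.67) and IFI27 (0.67) rose among 6 interferon response genes (camera adjusted p = 0.831). Of 12 cholesterol synthesis genes 4 rose and 2 fell (1 and 7 after quantile normalization), HMGCS1 at 0.73 and PCSK9 at -0.85 (camera adjusted p = 0.542). Of 4 lymphoid markers NKG7 (0.84), CD3D (0.48) and CD19 (0.38) rose, with 1 lower adjusted over the list alone (camera adjusted p = 0.548). Of 11 histone genes 4 rose and 1 fell (2 and 3 after quantile normalization), HIST1H4C at 1.65 (camera adjusted p = 0.955); HIST2H2BE (0.28) lost its call after quantile normalization and without hemin set 1 replicate 2 or set 3 replicate 3. Of 12 housekeeping genes 4 rose and 3 fell (5 and 4 after quantile normalization), UBC at 1.09 and RPLP0 at -0.55. Its test pointed down, as did that of the p53 list with a raw median of 0.08, and its own median was 0.04 raw and -0.06 with that of all genes subtracted (camera adjusted p = 0.881).

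ARID3a shRNA set 3 replicate 3, the only library with hemin whose nearest group of its set was untreated (0.443 against 0.529 to its own group), listed several hemin-responsive genes low: OSGIN1 at 14.7, CXCL8 at 5.60, SQSTM1 at 251, AKR1C1 at 219.9, MCM5 at 257 and HBE1 at 4055 TPM. The sum of RPPH1 and AL355075.4 was 83.4 to 805 TPM in the 9 scrambled libraries and 1.62 to 84.0 TPM in the other 27. For comparison, 59 genes lay wholly below and 18 wholly above the other 27 libraries in untreated cells, and 0 in the hemin or ARID3a shRNA libraries.

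Counts of genes from other splits of the same libraries were set beside the real ones. For hemin, 1 of 100 splits, the real one, gave as many as 8288 (highest other 1166), and for ARID3a shRNA 1 of 100 gave as many as 1020 (highest other 1). This argues against chance for both counts as far as replicates are independent, which is not stated. It holds only for TPM as deposited with all libraries in the fit, the 1 setting in which splits were run. The ARID3a shRNA count was far lower under several other settings given above, and chance was not tested there. With replicates averaged per set 5401 and 2 genes were called, so at the level of sets chance is not excluded for ARID3a shRNA. For scrambled shRNA 5 of 100 splits gave as many as 769 and the highest other gave 3707, so chance is not excluded and a structure of the samples is present. Set differences of scrambled and ARID3a shRNA had 0 genes, which every one of the 100 splits must reach, so the splits decide nothing there (highest others 2050 and 40). Within a set only 10 splits exist, too few for a share under 0.05: the real counts were 3871, 6734 and 4349 for hemin (1 split each as large; highest others 0, 90 and 1), 26, 11 and 295 for scrambled (2, 2 and 1 splits; 74, 2702 and 2) and 3, 386 and 2 for ARID3a shRNA (1 split each; 0, 1 and 1). The split with 74 exchanged scrambled set 1 replicate 1 with hemin replicate 2, and that with 2702 scrambled set 2 replicate 3 with hemin replicate 1, which points to a structure of those samples.

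The first pattern is that 12 of 36 libraries lie nearer to another group than to their own. Means of the own group rest on fewer libraries, as said above, which raises own distances somewhat. RPPH1 went against the label in 0 of 6 hemin and scrambled libraries of set 2. It was singled out because it split the libraries by these labels. That count was thus fixed in advance. In sets 1 and 3 taken alone, RPPH1 was at 0 and AL355075.4 at 83.4 to 805 TPM in scrambled libraries only. In set 2 AL355075.4 was at 508, 583 and 526 TPM in scrambled libraries and at 0.33, 1.32 and 0.52 TPM in hemin libraries. RPPH1 was there at 0 and at 32.9 to 82.7 TPM in turn. As far as both genes follow the shRNA given, these values argue against an exchange of labels between these 6 libraries. The share of mitochondrial transcripts had a Pearson r of -0.148 with the first principal component of deviations from group means (36 libraries, permutation p = 0.583, rho -0.067, permutation p = 0.741, r -0.043 without the 2 farthest). A varying mitochondrial share is not decided by this correlation. The distances leave out mitochondrial genes and subtract each library's median, while that component holds 20.7% of the variance of values without these steps. The share of small structured RNAs (RN7SK, RN7SL1, RN7SL2) correlated with that component at r = 0.602 (permutation p = 0.00551, adjusted p = 0.011 over 2 relations; rho 0.527, permutation p = 0.00873; r 0.452 without the 2 farthest libraries). Differences in library composition may thus contribute to that component. The same limit holds here, and a relation of these RNAs to the distances was not tested. The mean sum of these RNAs also differed between treatments, as given above. An exchange between hemin replicate 2 and ARID3a shRNA replicate 2 of set 3 cannot be told apart from poorly separated groups, because of 100 transcripts that part the groups in sets 1 and 2 only 43% lay on the side of the own label in the lower of both libraries. Treatment effects that are small beside the spread between libraries also stay open as a biological explanation and were not tested.

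The second pattern is the rise of MCM5 (from 70.3 ± 9.74 to 561 ± 145 TPM) while HMOX1, a textbook heme-induced gene and its neighbour with 0 genes between them, was listed at 0.0378 ± 0.0468 to 2.04 ± 0.591 TPM (log2 fold change 1.53 by limma). A rise of replication genes as a group is argued against, since the median of the 5 other MCM genes was 0.029 and they ranged from -0.16 to 0.25. Over the 27 libraries with hemin, MCM5 deviations from group means correlated with the heme and oxidative stress list without HMOX1 at r = 0.794 (permutation p = 0.00473, adjusted p = 0.00946; rho 0.672, permutation p = 0.00489; r 0.633 without the 2 farthest) and with the other MCM genes at r = 0.371 (permutation p = 0.24; rho 0.378, p = 0.147; r 0.079 without the 2 farthest). A candidate explanation is that reads of HMOX1, or of transcripts running from HMOX1 into MCM5, were counted for MCM5. A biological rise of MCM5 together with the stress genes would give the same correlation and stays open.

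The third pattern is the excess of negative regions on chromosome 22 in the authors' deposited table. Promoter content is argued against: the test was first written for promoter or GC content and narrowed to promoter content after its result, since gene sections do not measure GC, with a departure of -0.447 within gene sections in the authors' deposited table. Copy number differences between clones may contribute, but no copy number was measured. The median of chromosome 22 in the authors' deposited table departed by -0.432 from that of all regions, which is part of the same pattern and no separate support. Chromosome 17 in the authors' deposited table departed by -0.338 without an excess of calls (1.15% against 2.51% elsewhere). Start sites and other regions of the same 1 Mb bins differed by 0.309 (70 and 538 regions in 6 bins, permutation p = 0.0001, the smallest that 10000 permutations can give). This gap would go against copy number as the sole cause only if every copy were equally open at both kinds of region. That was not tested, so copy number as the sole cause stays undecided. GC content cannot be told apart without the sequence: chromosomes 16, 17, 19, 20 and 22 all had medians below that of all regions in the authors' deposited table, by -0.110 or more, but so had chromosome 9, outside this set, by -0.142. Genotype stays open as a biological explanation and was not tested, since the file holds no values per clone.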
